A study of Arabidopsis thaliana with 3 samples.

How the data were processed

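RNA was measured by sequencing ribosomal-RNA-depleted, stranded total RNA libraries from whole Arabidopsis thaliana seedlings aged 9 days. The 3 groups were WT (a Ws x Col-0 cross) and T12 and T34, which are populations of gip1 gip2 mutants. The series' design text gives them increasing severity of the root phenotype, read here as T34 being the more severe. GIP1 and GIP2 are small proteins of the gamma-tubulin complexes, which nucleate microtubules. Each group had 3 libraries, 9 in all. Per the labels the replicates were individual ones, and nothing further says how they were grown, so p-values measure the spread between these libraries only. The labels list the seventh library under both WT and T34 and the sixth under no group. The seventh was used as WT replicate 1, because the table comparing T12 with WT holds it among its 3 libraries that are not T12, and the sixth as T34 replicate 3, because it stands only in the table comparing T34 with WT.

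Per the submitters' processing notes the tools used were cutadapt 1.8.1, HISAT2 2.1.0, featureCounts 1.6.2 and DESeq2 1.22.2, with the build TAIR10. Their order, the annotation version, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so values of near-identical paralogs and of overlapping genes are uncertain. The authors deposited 2 tables of 30271 genes, T12 against WT and T34 against WT. Per the file headers each holds a mean normalized count, a log2 fold change with its standard error, a test statistic (score), a p-value and an adjusted p-value for each gene. Each also holds a normalized count per library. This deposited signal is the gene's count divided by a size factor for the library. The WT values and the mean counts were the same in both tables, so all 9 libraries were normalized together by the authors.

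At low values each library moved in steps of a fixed size, which is the worth of 1 read. At a tolerance of 0.01, 100% of the values came out as whole reads. The recovered totals were 20963358 to 30438933 reads per library. Reads of nuclear genes other than ribosomal RNA were 10069237 to 15286879 in the mutant libraries and 12346189, 646218 and 6287713 in WT replicates 1, 2 and 3. In WT replicate 2, 1 read was worth 11.687 normalized counts, so that library carries little information on genes of low expression.

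Since the tables hold normalized counts, the main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2 of the normalized count plus a pseudocount of 1. A count test had been planned for raw counts, with this test as the stated fallback for normalized values. All 9 libraries entered 1 fit with 3 comparisons, T12 with WT, T34 with WT, and T34 with T12. Genes with a normalized count of at least 10 in at least 3 libraries were tested, 20871 in all. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the scale of log2(value + 1), which understates the change of low genes. Errors of log2 fold changes are standard errors (SE) with n = 3 libraries per group, and errors of normalized counts are standard deviations (SD).

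The 25 gene lists, with 393 members, were fixed by locus code before the data were examined. Of these members, 4 (GIP1 among them) were not analysed here. For 383 members the listed name was found in the annotation and 7 loci had no name there and 3 another name, and 373 members passed the filter and were tested. Some single members are counted in their list and not reported here by name. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists within a comparison. The correlations estimated for the lists ranged from -0.034 (CDK inhibitors) to 0.706 (seed storage). Where the estimate is high, the p-values at 0.01 are too small. Lists were also tested with an estimated correlation and with fry. The camera test asks whether members change more than other genes, and fry whether they change at all. A list can thus pass fry where many genes change, and fry does not restore a lost camera call. Gene names came from the annotation of assembly TAIR10.1, which matched 29991 of the 30271 loci and was used only for names and neighbours. Process terms came from the notes in that annotation. Terms with 10 to 500 tested genes were compared with the tested genes that carry any term by a one-sided hypergeometric test, for genes called with an absolute log2 fold change of at least 1.

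The rule for the genes named in the text was also fixed before the data were examined. It takes GIP1 and GIP2 first. For each comparison it takes the 10 largest rises and the 10 largest falls among genes that passed the test, had a mean normalized count of at least 100 over the 9 libraries, and had every library of 1 group above every library of the other, leaving out chloroplast, mitochondrial, ribosomal RNA and transposable element genes. The rule had named a minimum on the CPM scale, and a minimum of 100 only for the case without values per library. The 100 was used here though values per library were at hand, so this threshold was not fixed in advance for such data. For each list it takes up to 4 members with the smallest adjusted p in T34 against WT. Any other gene is named as chosen after its values were seen.

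Alternatives were other size factors, filters and pseudocounts, other subsets of libraries and genes, and count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. edgeR's quasi-likelihood test on the recovered reads called 9610, 10434 and 1385 genes in T12 against WT, T34 against WT and T34 against T12. The test was tried on simulated counts of 20871 genes with 100 genes changed 2-fold and 100 changed 4-fold. For T12 against WT it recovered 53% of the 2-fold and 82% of the 4-fold changes, for T34 against WT 46% and 86%, and for T34 against T12 47% and 84%, with 5, 7 and 2 false calls. The real comparisons with WT called far more genes (8382 in T12 and 9428 in T34), so these rates do not carry over to them.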

Results

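The transcriptomes of whole seedlings were compared between WT and T12 and T34, populations of gip1 gip2 mutants of which T34 has the more severe root growth phenotype, with 3 libraries per group. The libraries held 20963358 to 30438933 reads. The share of reads from ribosomal RNA was 1.16% ± 0.471 (SD, n = 3) in T12, 46.9% ± 2.27 in T34 and 55.7% ± 37.1 in WT. In WT replicate 2 it was 95.7% (95% Wilson interval 95.70 to 95.72%, counting error only), which left 646218 reads of other nuclear genes. Of the reads other than ribosomal RNA, chloroplast genes took 34.2% ± 1.18 in T12, 21.9% ± 0.745 in T34 and 46.0% ± 6.77 in WT. Across genes, log2 values of T12 and T34 libraries correlated at 0.907 to 0.963, values of WT and T12 libraries at 0.643 to 0.687, and values of WT and T34 libraries at 0.593 to 0.637. Within groups the range was 0.945 to 0.979 for T12, 0.968 to 0.985 for T34 and 0.888 to 0.976 for WT, across 12896 genes, which are not independent replicates. In a check for copied libraries, those of a group differed by more than sampling noise, with chi-square values per degree of freedom of 5.51 to 31.88. Any separate samples would do so, and the check says nothing more.

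**Figure D1:**
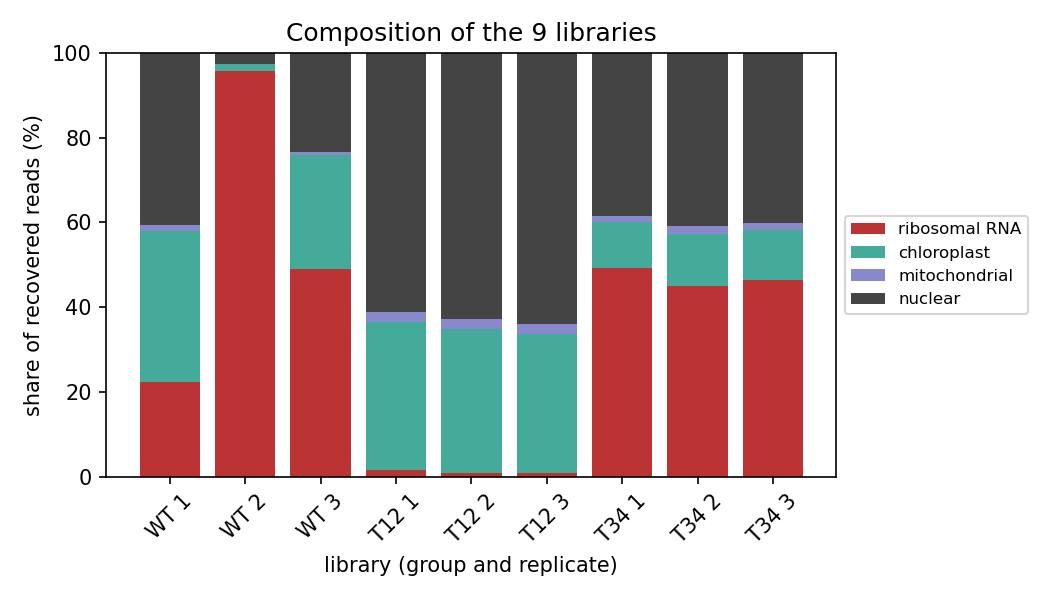
Share of recovered reads (%) from ribosomal RNA, chloroplast, mitochondrial and nuclear genes in each of the 9 libraries, drawn as stacked bars. Ribosomal RNA took 95.7% of WT replicate 2 and a mean of 1.16% in T12.

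GIP1, the first of the mutated genes, is not analysed here. GIP2 (AT1G73790) was near the floor in every library. It had 4, 1 and 0 reads in WT replicates 1 to 3, 1 read in each T12 library, and 2, 3 and 5 reads in T34 replicates 1 to 3. GIP2 therefore gave no check of the labels.

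The comparison of T12 with WT asked how the transcriptome of the population with the milder phenotype differs from that of WT. Of the list members tested, 14 of 15 jasmonate and wounding, 10 of 11 heat shock and 10 of 12 flavonoid genes were higher in T12. The jasmonate synthesis gene OPR3 was 19.1-fold higher. These list calls by camera were lost with an estimated correlation (adjusted p = 0.141, 0.265 and 0.265). These lists passed fry (adjusted p = 2.19e-05, 0.000343 and 0.000343). It asks only whether members change, as 8382 of the 20871 genes tested did in T12. Evening-phased clock genes were lower, with PRR5 12.5-fold lower, and so were the dormancy-associated genes AT2G33830 and DYL1. The camera call of the clock list was also lost with an estimated correlation (adjusted p = 0.359), and the list passed fry (4.63e-05). Of 20871 genes tested with limma, 4827 were higher and 3555 lower in T12, and with upper quartile factors 4215 and 4617, so which direction has more genes depends on the scaling. Of the first counts, 3032 and 1378 had an absolute log2 fold change of at least 1.

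Of the 15 tested jasmonate and wounding genes, 14 rose in T12 and 1 (ORA59) did not pass, and 15 rose when adjusted over the list alone (median log2 fold change 4.47, camera adjusted p = 3.3e-09, adjusted p = 0.141 with an estimated correlation). The list holds 18 members, of which PDF1.2, PDF1.2b and PDF1.2c did not pass the filter on low values and were not tested. A member low in WT passes that filter only if it is higher in the mutants, so these shares favour genes that rose. OPR3, which encodes a jasmonate biosynthetic reductase, rose by 4.26 ± 0.27 on the log2 scale (SE, n = 3, adjusted p = 6.75e-06 by limma). JAZ1, a repressor of jasmonate signalling, rose by 4.47, and the vegetative storage protein genes VSP1 and VSP2 by 2.2 and 3.57. Rises and falls are ranked here and below only among genes that meet the rule for named genes, which asks for a mean normalized count of at least 100 over the 9 libraries, groups that do not overlap, and no ribosomal RNA, organelle or transposable element gene. Under it the largest rises in T12 included the aminotransferase gene TAT3, from 55.2 ± 83.7 to 4123 ± 1163 normalized counts (SD, n = 3), and FAMT, from 15.2 ± 17.2 to 1557 ± 655 normalized counts. AT3G44870 had the largest rise, at 8.22 ± 0.72. HSD2, AT1G65490, CYP82C2, PEN1, AT4G19500 (annotated as RPP2A) and AT1G54020 were also among the 10 largest rises, at 7.48, 7.36, 7.27, 7.14, 6.82 and 6.77 on the log2 scale. JAZ8, another of these 10, had 4.53 ± 6.21 normalized counts in WT, from 1 read in each library, and 424 ± 18.9 in T12. WT libraries held few reads of most of these genes, so the size of the rises is uncertain.

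Of 16 touch and mechanical stimulation genes, 11 rose and 0 fell in T12, both over all genes and adjusted over the list alone (median 2.21, camera adjusted p = 0.00169, adjusted p = 0.37 with an estimated correlation). WRKY40 rose by 4.95 and the calmodulin-like gene CML12 by 3.74. Of 11 heat shock genes, 10 rose by both adjustments (median 4.18, camera adjusted p = 0.000128, adjusted p = 0.265 with an estimated correlation), with HSP70 up by 4.97 ± 0.58 and HSP90.1 by 4.68 ± 0.54. Of 12 flavonoid and anthocyanin genes, 10 rose by both adjustments (median 3.14, camera adjusted p = 0.000113, adjusted p = 0.265 with an estimated correlation). Chalcone synthase, CHS, went from 22.9 ± 21.1 to 566 ± 316 normalized counts, and the anthocyanin regulator PAP1 (AT1G56650) rose by 4.68. Of 16 glucosinolate genes, 13 rose and 1 (TGG2) fell by both adjustments (median 2.5, camera adjusted p = 7.01e-06, adjusted p = 0.141 with an estimated correlation), among them SOT16 at 2.62 and CYP79F2 at 3.07.

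Of 14 salicylic acid defence genes, 11 rose in T12, and 12 adjusted over the list alone (median 1.87, camera adjusted p = 0.00018, adjusted p = 0.141 with an estimated correlation). SID2, which encodes the isochorismate synthase of salicylic acid synthesis, rose by 2.03, and PAD4 by 1.94. Of 10 phosphate starvation genes, 7 rose and 1 (PHO2) fell, and 8 rose and 1 fell adjusted over the list alone (median 1.72, camera adjusted p = 0.00925, adjusted p = 0.359 with an estimated correlation), with SQD1 at 1.62 and PHT1;4 at 2.06. Of 11 mitochondrial and oxidative stress genes, 7 rose and 1 (GSTU25) fell by both adjustments (median 1.42, camera adjusted p = 0.0171, adjusted p = 0.265 with an estimated correlation). The superoxide dismutase gene CSD1 rose by 2.56 and the ascorbate peroxidase gene APX1 by 2.08.

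All 10 circadian clock genes tested passed the test in T12, 3 higher (CCA1, LHY and PRR9) and 7 lower, also adjusted over the list alone (median -1.85, camera adjusted p = 0.00925, adjusted p = 0.359 with an estimated correlation and 0.147 without WT replicate 2). Members moved both ways, with a mean log2 fold change of -0.36. The morning-phased gene CCA1 rose from 58.8 ± 31.5 to 1703 ± 149 normalized counts. PRR5 fell from 579 ± 39.9 to 45.3 ± 4.37, and the evening-phased genes TOC1 and LUX changed by -2.48 and -2.34 on the log2 scale. Under the rule, the largest falls included FKF1 and COR27, at -5.76 and -5.96.

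Under the rule, the largest fall in T12 was that of AT2G33830 (annotated DRM2, of the dormancy-associated family), from 11134 ± 776 to 37.0 ± 15.9 normalized counts. The dormancy-associated gene DYL1 fell from 6144 ± 647 to 140 ± 31.9. MEE14, WCRKC1, AT3G62550 and BT2 changed by -6.44, -6.1, -5.92 and -5.56. AT3G28320, a gene of unknown function, went from 676 ± 52.1 to 2.76 ± 1.45. AT1G07017, annotated as non-coding, changed by -8.05, with 165.21, 11267 and 474.12 normalized counts in WT replicates 1 to 3, so its WT level was highest in the library with most ribosomal RNA.

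Of 18 gamma-tubulin and microtubule nucleation genes, 6 fell and 0 rose by both adjustments (median -0.20, camera adjusted p = 0.0111, adjusted p = 0.265 with an estimated correlation). AUG8, of the augmin family, went from 385 ± 55.5 to 157 ± 24.4 normalized counts, and AUG6 changed by -0.61. Of 17 nuclear envelope genes, 1 rose and 2 (WIP3, AT3G13360, and KAKU4) fell, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.613). NEAP2, a nuclear envelope-associated protein gene, rose by 1.45 ± 0.11, and WIP3 changed by -0.54. Of 18 centromere, kinetochore and cohesin genes, 1 rose (SYN1, at 1.34) and 2 fell (SMC3, AT2G27170, at -0.74, and SGO1) by both adjustments (camera adjusted p = 0.613).

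The other 13 lists did not pass camera in T12, with adjusted p from 0.613 to 0.902. Counts adjusted over the list alone were the same except where given. Members beyond the rule for named genes were named after their values were seen. Of the 20871 genes tested 8382 were called in T12, so called members alone do not set these lists apart. Of 15 CDK inhibitor and endocycle genes, KRP6 rose by 1.87 and 2 fell (KRP4 at -1.54, and SMR2), with 1 fall over the list alone. Of 17 auxin genes, 5 rose (IAA19, IAA1, IAA5, GH3.1 and GH3.3) and 4 fell (PIN4 at -1.46, PIN7 at -1.73, AUX1 and DFL1). Of 18 osmotic stress and abscisic acid genes, 7 rose and 3 fell (COR15B at -5.24, COR15A and COR47), with 8 rises over the list alone, RD26 among them at 1.86. Of 11 iron status genes, 2 rose (FER3 and IMA1) and 3 fell, namely BHLH39, the iron uptake regulator FIT at -2.58 and the transporter IRT1 at -3.29. Of 10 root endodermis and uptake genes, 2 rose (PHT1;1 and AMT1;2) and 4 fell, among them CASP2 and CASP5, at -1.18 for CASP5. Of 13 root hair genes 2 rose (RHD6 and LRX2) and 1 fell (GL2, -1.23), and 0 passed over the list alone. Of 9 root meristem genes WOX5 rose and JKD fell, at -1.25. Of 19 photosynthesis genes, 6 rose and 6 fell, with 7 falls over the list alone. Of 26 DNA damage genes 3 rose (AGO2, GMI1 and PARP2) and 4 fell (LIG4, KU80, PARP1 and RAD50). Of 19 DNA replication genes 2 rose (PCNA1 and MCM6), with 1 over the list alone. Of 25 G2/M genes 3 rose (TES, CDC20.1 and CDKB1;1) and 1 fell (CYCB2;3), with 2 rises over the list alone. Of 11 cellulose synthase genes 3 rose (CESA5 by 1.41, CESA6 and CESA8) and CSI1 fell, and of 12 seed storage genes OLEO2 rose. Among the genes named for T12, the calls of SYN1, CASP2, CASP5, CDKB1;1, CESA6, CESA8, COR47, CSI1, GL2, IMA1, KAKU4, KU80, LRX2, PARP1, RAD50, RHD6, SMR2 and TGG2 were lost when at least 1 library was left out. For CSI1, GL2 and KU80 this was a single library (T12 replicates 3, 1 and 2). Median and mean had opposite signs for the nuclear envelope, centromere, CDK inhibitor, G2/M, photosynthesis and cellulose synthase lists.

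The term tests use the same calls as above and treat genes as independent, so genes that move together make their p-values too small. Of 61 genes with the term response to wounding, 36 were among those higher by at least 1 in T12, against 9.73 by chance (adjusted p = 2.83e-12). Response to heat had 30 of 57 genes against 9.09. Among genes lower by at least 1, response to biotic stimulus had 8 of 19 (adjusted p = 0.00283), starch catabolic process 6 of 11 (adjusted p = 0.00305) and circadian rhythm 6 of 13 (adjusted p = 0.00676). Defense response had genes on both sides, 94 of 273 higher by at least 1 against 43.6 by chance (adjusted p = 2.83e-12) and 34 lower by at least 1 against 17.5 (adjusted p = 0.00919).

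**Figure D2:**
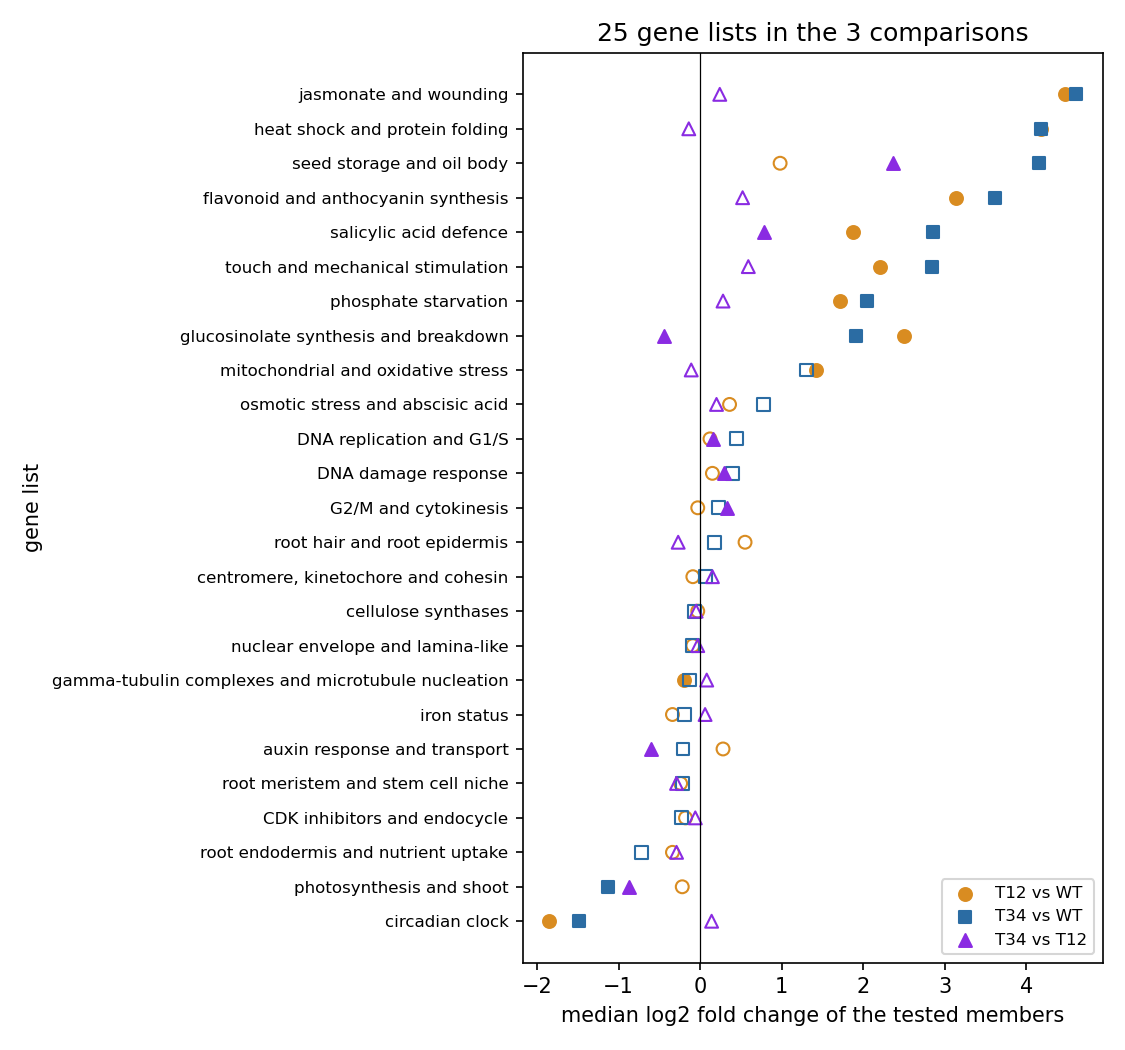
Median log2 fold change (x axis) of the tested members of each of the 25 gene lists (y axis) in the 3 comparisons, with filled symbols where camera gave an adjusted p under 0.05. Jasmonate and wounding genes lie at 4.47 and 4.61 in the mutants against WT, and at 0.24 between T34 and T12.

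The comparison of T34 with WT asked the same of the population with the more severe phenotype. Of the list members tested, 15 of 15 jasmonate, 12 of 14 salicylic acid and 10 of 11 heat shock genes were higher in T34. So were 11 of 12 flavonoid and 9 of 12 seed storage genes, and OPR3 was 22.5-fold higher. These list calls by camera were lost with an estimated correlation (adjusted p = 0.189, 0.189, 0.348, 0.348 and 0.559). These lists passed fry (adjusted p = 2.91e-05, 2.91e-05, 0.000396, 0.000205 and 0.02). It asks only whether members change, as 9428 of the 20871 genes tested did in T34. Lower were 12 of 19 photosynthesis genes and the evening-phased clock genes, with PRR5 14.3-fold lower. The camera calls of these 2 lists were also lost with an estimated correlation (adjusted p = 0.512 and 0.467), and the lists passed fry (0.0068 and 8.99e-05). Of 20871 genes tested with limma, 5262 were higher and 4166 lower, of which 3308 and 1945 had an absolute log2 fold change of at least 1. With upper quartile factors the counts were 4510 higher and 5291 lower, so here too the direction with more genes depends on the scaling.

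All 15 jasmonate and wounding genes tested, of 18 listed, rose in T34, also adjusted over the list alone (median 4.61, camera adjusted p = 1.26e-08, adjusted p = 0.189 with an estimated correlation). VSP2 went from 121 ± 49.8 to 2516 ± 149 normalized counts (SD, n = 3). VSP1, JAZ1 and OPR3 rose by 2.81, 4.61 and 4.49 on the log2 scale. The thionin gene THI2.1 rose by 7.1 ± 0.99 (SE, n = 3, adjusted p = 0.000424 by limma) and TAT3 by 7.14. Under the rule, the lipase gene AT1G54020 had the largest rise, at 8.29 ± 1.03. HSD2, AT3G44870, AT1G65490, CYP82C2, RLP24 and the lectin gene JAL23 were also among the 10 largest rises, at 7.68, 7.82, 7.44, 7.31, 7.1 and 7.47.

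Of 14 salicylic acid defence genes, 12 rose in T34 by both adjustments, over all genes and over the list alone (median 2.85, camera adjusted p = 4.83e-05, adjusted p = 0.189 with an estimated correlation). The glucanase gene PR2 went from 1.26 ± 1.27 to 463 ± 109 normalized counts and PR5 from 7.01 ± 4.14 to 178 ± 43.7, while SID2 and PAD4 rose by 2.08 and 2.15. Of 16 touch genes, 12 rose, and 13 adjusted over the list alone (median 2.84, camera adjusted p = 0.000565, adjusted p = 0.422 with an estimated correlation), with WRKY40 at 5.62 and CML12 at 3.68. Of 11 heat shock genes, 10 rose by both adjustments (median 4.18, camera adjusted p = 0.000408, adjusted p = 0.348 with an estimated correlation), with HSP70 at 5.33 and HSP90.1 at 4.79. Of 12 flavonoid genes, 11 rose by both adjustments (median 3.61, camera adjusted p = 0.000177, adjusted p = 0.348 with an estimated correlation), with CHS at 5.66 and PAP1 (AT1G56650) at 4.95.

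Of 16 glucosinolate genes, 12 rose and 2 (TGG1 and TGG2) fell in T34 by both adjustments (median 1.91, camera adjusted p = 0.000565, adjusted p = 0.348 with an estimated correlation), with SOT16 at 2.41 and CYP79F2 at 2.69. Of 10 phosphate starvation genes, 7 rose by both adjustments (median 2.04, camera adjusted p = 0.00121, adjusted p = 0.348 with an estimated correlation), with PHT1;4 at 2.93 and the phosphatase gene PAP17 at 2.87. Of 12 seed storage and oil body genes, 9 rose, and 11 adjusted over the list alone (median 4.15, camera adjusted p = 0.00572, adjusted p = 0.559 with an estimated correlation). The oleosin gene OLEO2 went from 45.2 ± 42.9 to 1231 ± 428 normalized counts, and the cruciferin gene CRA1 from 711 ± 851 to 9332 ± 3558.

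Of 19 photosynthesis genes, 12 fell and 1 (LHCB2.2) rose in T34, and 14 fell and 1 rose adjusted over the list alone (median -1.13, camera adjusted p = 0.000191, adjusted p = 0.512 with an estimated correlation). The photosystem I antenna genes LHCA1, LHCA2 and LHCA3 changed by -1.52, -1.45 and -1.67. The term photosynthesis held 29 of 64 genes lower by at least 1, against 5.97 by chance (adjusted p = 1.24e-11). Chloroplast genes took 21.1 to 22.6% of the reads other than ribosomal RNA in T34 libraries, against 39.2 to 52.8% in WT libraries. FBA5, a fructose-bisphosphate aldolase gene, and RbcX1, a Rubisco chaperone gene, were among the 10 largest falls under the rule, at -6.35 and -6.24.

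All 10 clock genes passed in T34, 3 higher (CCA1, LHY and PRR9) and 7 lower, also adjusted over the list alone (median -1.48, camera adjusted p = 0.0191, adjusted p = 0.467 with an estimated correlation and 0.198 without WT replicate 2). CCA1 rose by 5.02 ± 0.31, and PRR5, TOC1 and LUX changed by -3.83, -2.10 and -2.73. FKF1 and COR27 changed by -5.72 and -5.79. The term circadian rhythm, which passed among lower genes in T12, held 5 of 13 here and did not pass (hypergeometric test, adjusted p = 0.134). AT2G33830 fell from 11134 ± 776 to 68.1 ± 15.5 normalized counts, and SEN1 (AT4G35770), a gene of dark-induced senescence, from 11518 ± 2459 to 204 ± 24.4. AT3G28320 had the largest fall under the rule, at -8.41 ± 0.54, and WCRKC1, MEE14 and AT3G62550 changed by -6.13, -6.11 and -6.03.

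**Figure D3:**
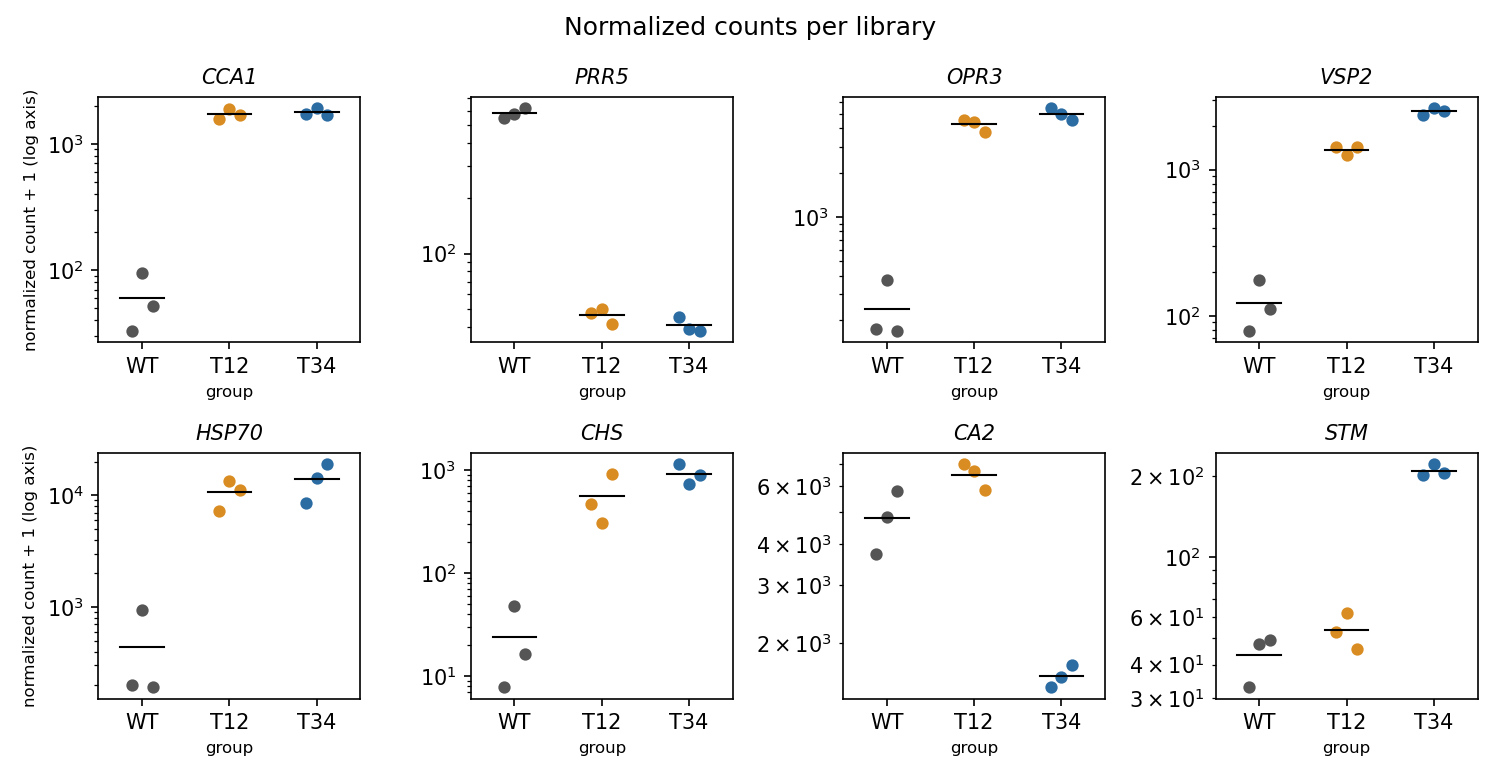
Normalized count plus 1 on a log axis for 8 genes in each library of WT, T12 and T34, with points for libraries and lines for group means. CCA1, OPR3, VSP2, HSP70 and CHS were higher and PRR5 lower in every T12 and T34 library than in every WT library, while CA2 and STM set T34 apart from T12.

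In T34 the gamma-tubulin list had 4 genes lower of 18 tested (AUG8 at -1.44, AUG6, AUG3 and NEDD1), and 3 adjusted over the list alone (camera adjusted p = 0.145, 0.00612 by fry). Of 17 nuclear envelope genes 1 rose (NEAP2, 1.3) and 1 fell (WIP3, AT3G13360, -0.89) by both adjustments, and of 18 centromere genes 1 fell (SMC3, AT2G27170), with camera adjusted p = 0.553 and 0.832. Of 26 DNA damage genes, 9 rose and 4 fell (LIG4, KU80, RAD50 and PARP1), and 11 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.185, 0.00612 by fry). GMI1 rose by 1.76 ± 0.16, AGO2 by 2.03 and PARP2 by 0.94. Of 19 DNA replication genes 7 rose (MCM6 by 0.69, PCNA1 by 0.96), and 6 adjusted over the list alone (camera adjusted p = 0.22, 0.0226 by fry). Of 25 G2/M genes 6 rose and 1 (CYCB2;3) fell by both adjustments (camera adjusted p = 0.185, 0.0453 by fry), with CDC20.1 at 0.87 and TES at 1.45.

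The other 9 lists did not pass camera in T34, with adjusted p from 0.0695 to 0.841. Counts over the list alone were the same except where given, and members beyond the rule were named after their values were seen. Of 11 mitochondrial and oxidative stress genes 7 rose (CSD1 by 2.66) and 2 fell (GSTU25 at -1.48, and UPOX), with camera adjusted p = 0.0695. Of 17 auxin genes 5 rose (among them IAA5, GH3.3 and GH3.5) and 7 fell, with PIN4 at -1.84 and PIN7 at -2.37, and 8 fell over the list alone. Of 18 osmotic stress genes 8 rose (RD26 by 2.04) and 4 fell (COR15B at -5.7, COR15A, COR47 and ERD1). Of 15 CDK inhibitor genes 2 rose (KRP6 by 1.37, and KRP3) and 2 fell (KRP4 at -1.6, and KRP1). Of 11 iron status genes 4 rose (FER1 by 1.75, FER3, IMA1 and PYE) and 3 fell (FIT at -2.81, IRT1 at -4.31, and BHLH39). Of 10 root endodermis and uptake genes 2 rose (PHT1;1 by 1.47, and AMT1;2) and 5 fell (among them CASP2, CASP4 and CASP5 at -1.89). Of 13 root hair genes 1 fell (GL2, -1.11), and 0 passed over the list alone. Of 9 root meristem genes PLT3 rose and 2 fell (JKD at -1.7, and BBM). Of 11 cellulose synthase genes 3 rose (CESA5 by 1.42, CESA7 and CESA8) and 4 fell (CSI1, COBRA, CESA1 and CESA3). Among the genes named for T34, the calls of BBM, CASP2, CASP4, CESA1, CESA3, CESA7, CESA8, COBRA, CYCB2;3, ERD1, GH3.3, GH3.5, GL2, IAA5, KRP1, KRP3, NEDD1, PARP1, PLT3 and PYE were lost when at least 1 library was left out. For CYCB2;3 and IAA5 this was a single library (T34 replicates 2 and 1). Median and mean had opposite signs for the nuclear envelope and cellulose synthase lists, and median and camera's direction for the centromere and root hair lists.

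Log2 fold changes against WT in T12 and T34 correlated across 20871 genes at r = 0.918, with a covariance of 1.49. Unchanged groups simulated against shared WT libraries gave r = 0.498 and a covariance of 0.0588 over 100 simulations, a difference in covariance of 1.43. Signs were the same for 87.5% of genes, against 66.6% in the simulations. In both mutants 4171 genes were called higher and 2912 lower, where independent lists would share 1217 and 710, and 15 were called in opposite directions. The simulations shared a mean of 0 calls, but their groups were unchanged, so that count was given in advance and sets no scale. The 3 WT libraries cannot be split so that each part keeps 2, so part of the excess in shared calls over independent lists may come from the shared controls.

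The comparison of T34 with T12 asked whether the populations of differing severity differ from each other. Lower in T34 than in T12 were 8 of 19 photosynthesis, 4 of 17 auxin and 3 of 16 glucosinolate genes. These list calls by camera were lost with an estimated correlation (adjusted p = 0.188 for each), and the lists passed fry (adjusted p = 0.0176 for each). The carbonic anhydrase gene CA2 was 4.08-fold lower. Libraries of T12 and T34 also stand apart in the share of ribosomal RNA (1.16% and 46.9%), so these differences cannot be separated from it. The meristem gene STM was 3.93-fold higher, and the defence gene PR5 and the pectate lyase gene AT3G27400 were higher too. limma called 179 genes higher and 318 lower in T34, 497 in all, and 390 of these remained in a fit of nuclear genes without ribosomal RNA. The count was 1882 without WT replicate 2, which enters this comparison only through the shared spread. It was 21, 17 and 114 without T12 replicates 1, 2 and 3, and 15, 14 and 141 without T34 replicates 1, 2 and 3. AT3G27400, CA1, CA2 and AT2G29290 passed without each library in turn. The other calls named below were each lost without at least 1 library.

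Of 19 photosynthesis genes, 8 fell in T34 relative to T12 and 0 rose, and 18 fell adjusted over the list alone (median -0.87, camera adjusted p = 7.74e-17, adjusted p = 0.188 with an estimated correlation). LHCA1, LHCA2 and PSAD1 changed by -0.97, -0.87 and -1.01. Of the reads other than ribosomal RNA, chloroplast genes took 34.2% ± 1.18 in T12 and 21.9% ± 0.745 in T34. The carbonic anhydrase genes CA1 and CA2 were among the 10 largest falls of genes with a mean normalized count of at least 100 that meet the rule. Called genes below that mean fell by more. CA2 had 4782 ± 1035 normalized counts in WT, 6479 ± 608 in T12 and 1584 ± 123 in T34 (SD, n = 3), and CA1 had 4410 ± 1075, 5830 ± 1098 and 1158 ± 205. The term photosynthesis held 10 of 64 genes lower by at least 1 against 0.518 by chance, and response to red light 7 of 17 against 0.138.

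Of 17 auxin genes, 4 fell in T34 relative to T12, and 8 adjusted over the list alone (median -0.6, camera adjusted p = 2.67e-06, adjusted p = 0.188 with an estimated correlation). IAA29, an auxin response gene, was the largest fall under the rule, at -2.95 ± 0.63 (SE, n = 3, adjusted p = 0.0486 by limma). IAA29 had 275 ± 241 normalized counts in T12. The other 3 were IAA6 (14.4 ± 10.8 normalized counts in T12 and 0.792 ± 0.0451 in T34), IAA19 (-1.42) and IAA1 (-1.29), named after their values were seen. The T34 value of IAA6 is that of 1 read in each library (worth 0.791, 0.747 and 0.837 in replicates 1 to 3). Its small SD reflects the size factors only, and the size of its fall is uncertain. Of 16 glucosinolate genes, 3 fell (CYP79F1 and the myrosinase genes TGG1 and TGG2, at -1.24, -0.86 and -1.48, named after their values were seen), and 6 adjusted over the list alone (median -0.44, camera adjusted p = 2.67e-06, adjusted p = 0.188 with an estimated correlation). The 10 largest falls under the rule also held the arabinogalactan protein gene AGP30 at -2.20, the defensin-like gene AT3G05727 at -2.54, AT4G22490 at -2.42, AT3G21330 (bHLH87) at -2.40, AT2G29290 at -2.25, AT4G13575 at -2.24 and AT4G38860 at -2.18.

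STM, which maintains the shoot meristem, had 42.4 ± 9.08 normalized counts in WT, 52.6 ± 8.05 in T12 and 208 ± 10.7 in T34, a difference of 1.98 ± 0.2 between T34 and T12 (adjusted p = 0.00556). LOG5, of cytokinin activation, differed by 1.99, and the pectate lyase gene AT3G27400 by 2.97 ± 0.23. RLP24, AT1G03820, OZF1, AT3G44970, DYL1 and AT5G60250 were also among the 10 largest rises under the rule, at 3.39, 2.04, 1.61, 1.54, 1.44 and 1.4. The largest under the rule, AT1G07017 at 6.27, had 2.72 ± 1.11 normalized counts in T12 and 282 ± 50.1 in T34, groups with 1.16% and 46.9% of ribosomal RNA.

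Of 14 salicylic acid defence genes, PR5 rose in T34 relative to T12, by 2.92 ± 0.48 (adjusted p = 0.023), and 3 rose adjusted over the list alone (median 0.78, camera adjusted p = 0.00118, adjusted p = 0.188 with an estimated correlation). Of 12 seed storage genes 0 passed over all genes and 6 rose adjusted over the list alone (median 2.37, camera adjusted p = 1.16e-05, adjusted p = 0.46 with an estimated correlation and 0.161 by fry). For OLEO2 the log2 difference was 1.76 ± 0.65 (adjusted p = 0.225). The G2/M list (median 0.33, camera adjusted p = 1.58e-05, adjusted p = 0.348 with an estimated correlation and 0.084 by fry) had 0 of 25 members past the threshold, over all genes or over the list alone. The DNA damage list (median 0.29, camera adjusted p = 0.000363, adjusted p = 0.219 with an estimated correlation) had 0 of 26 over all genes and 1 adjusted over the list alone. The DNA replication list (median 0.16, camera adjusted p = 0.026, adjusted p = 0.553 with an estimated correlation and 0.205 by fry) had 1 of 19 by both adjustments, CYCD3;1 at 0.58. The other 17 lists did not pass, with camera adjusted p from 0.0818 to 0.668, among them jasmonate and wounding (median 0.24), heat shock (median -0.14) and the clock (median 0.14). In these lists CAT2 (AT4G35090) fell and PHO2 rose over all genes, at -0.88 and 1.04, both named after their values were seen. Adjusted over the list alone, 2 jasmonate genes rose and 1 fell, 3 clock genes rose, 2 mitochondrial and oxidative stress genes fell and 1 phosphate starvation gene rose.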

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

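The tests of the clock and of the jasmonate genes were chosen after the results were seen, and the splits of the libraries before. The effect against WT differed between T34 and T12, tested directly, for 497 genes, and 15 genes were called against WT in opposite directions in T12 and T34. Among them CA2 had log2 fold changes of 0.46 in T12 and -1.57 in T34. Its rise in T12 was only just under the threshold (limma adjusted p = 0.0478). The photosynthesis genes RBCS3B and GAPA, named after their values were seen, had 0.67 and 0.57 in T12 and -0.55 and -0.44 in T34. Without T12 replicate 1 the GAPA call in T12 was lost, and without WT replicate 3 those of GAPA and RBCS3B in T34, among other single libraries. Among the lists, T34 and T12 differed by camera for DNA damage response (adjusted p = 0.000363), DNA replication and G1/S (0.026), G2/M and cytokinesis (1.58e-05), salicylic acid defence (0.00118), auxin response and transport (2.67e-06), photosynthesis and shoot (7.74e-17), glucosinolates (2.67e-06) and seed storage (1.16e-05). All 8 were lost with an estimated correlation (adjusted p from 0.188 to 0.553), and DNA replication, G2/M and seed storage did not pass fry either. With 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. In fits of the 6 libraries compared, only 1 of the 10 splits, the real one, gave as many genes, with 6524 for T12 against WT, 8046 for T34 against WT and 2144 for T34 against T12, and the highest of the others gave 0 in each.

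The clock genes separated the mutants from WT. The median log2 fold change of the morning-phased genes CCA1, LHY and PRR9 lay above that of the evening-phased genes PRR5, TOC1, LUX, ELF4 and GI by 7.44 in T12 and 7.75 in T34 against WT, and by 0.24 in T34 against T12. Ribosomal RNA left in the libraries is argued against as the cause, since T12 and T34 differ in it (1.16% and 46.9%) and the clock list's median absolute change between them was 0.38, against 2.77 between T12 and WT. A harvest of WT at another time of day may account for the pattern, and so may a changed clock in the mutants. These cannot be told apart, since every WT library stands on 1 side (-4.26, -3.04 and -4.17 for morning minus evening genes) and every mutant library on the other (3.36 to 4.21). The harvest times were not used here, so genes that follow the time of day may be among those called against WT.

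Jasmonate and wounding genes were higher in both mutants. Brief handling just before freezing would leave slow outputs little changed. The outputs VSP1, VSP2, THI2.1, DFR, LDOX and UF3GT had a median log2 fold change of 4.75 in T12 and 5.46 in T34. They were picked from the jasmonate and flavonoid lists after these were seen to rise. Their high median was thus known in advance, and brief handling is not excluded. The touch and mechanical stimulation list, fixed in advance, also rose and gives no argument against handling. Of its 16 genes 11 rose in T12 and 12 in T34, and 0 fell (medians 2.21 and 2.84). The low depth of WT replicate 2 is argued against by medians of 4.81 and 4.75 for the list without that library, and the ribosomal RNA share by a median absolute change of 0.5 between T34 and T12. Harvest at another time of day may also contribute and cannot be told apart from genotype, since within a group the clock difference ranged over at most 1.22 (in WT, with replicate 2 the highest). The jasmonate list mean was also highest in that library (5.5, 6.64 and 5.84 in WT replicates 1 to 3), which reads shared with the mutant libraries could give as well. A response to the loss of both GIP proteins, to longer-lasting stress or to growth conditions stays open and was not tested.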

How the results depend on the processing

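Some settings were chosen after the data were seen, namely TMM factors, array weights, the robust limma variance, edgeR with TMM factors, edgeR on nuclear reads, limma-voom, nuclear genes alone, edgeR without WT replicate 2, and the sixth and seventh libraries left out together. Counts against WT stayed within 1.5 times of 8382 (T12) and 9428 (T34), except with an absolute log2 fold change of at least 1 (4410 and 5253). Without each library in turn they were 6337 to 10181 and 7330 to 11156. Upper quartile factors shifted the median of all genes from 0.06 to -0.04 in T12 and to -0.06 in T34, and lowered the share of calls that were higher from 57.6% to 47.7% and from 55.8% to 46%. The 497 calls between T34 and T12 became 285 at an absolute log2 fold change of at least 1, 2144 with only those 6 libraries, 1568 with DESeq2, 1385 with edgeR, 1386 with edgeR and RLE factors, 1408 with its robust fit, 1251 with edgeR on nuclear reads, 1633 with limma-voom, 6297 with array weights (0.086 for WT replicate 2), 2059 with edgeR without WT replicate 2, and 171 without the sixth and seventh libraries, and 14 to 1882 without each library in turn (1882 without WT replicate 2, 21, 17 and 114 without T12 replicates 1 to 3, 15, 14 and 141 without T34 replicates 1 to 3). WT replicate 2 enters this comparison only through the spread shared by all groups, and leaving it out gave 1882 calls. Without WT replicates 1 and 3 the counts were 599 and 531. The spread of WT replicate 2 thus lowered the count of 497 and the list member counts between T34 and T12. The cause of the lower counts without a T12 or T34 library was not tested, though leaving out a library of either group leaves fewer samples. The correlation of the effects against WT moved from 0.918 to 0.898 with no filter. An estimated correlation ended the camera call in all 28 of the 75 list results that had it. By fry, which asks only whether members change, 3 of the 28 did not pass. They were DNA replication at 0.205, G2/M at 0.084 and seed storage at 0.161, all in T34 against T12. Lists that passed fry and not camera were 8, all in T34 against WT. They were gamma-tubulin, DNA damage, DNA replication, G2/M, auxin (0.00612), CDK inhibitors (0.0125), osmotic stress (0.0228) and mitochondrial and oxidative stress (2e-04). Leaving out WT replicate 2 ended 2 (both for the clock list), and TMM factors or leaving out genes near GIP1 and GIP2 changed none. Of 248 results for named genes, 168 kept their side of the threshold under every setting and none that was called changed direction. Leaving out a library ended 316 of these calls over all such fits and added 3, and the other settings ended 134 and added 20. The authors' deposited table called 8781 genes for T12 and 9644 for T34 at an adjusted p under 0.05, of which 7786 and 8606 were called here too, all in the same direction. No paired analysis was possible because the columns carry no shared replicate numbers. Depth limits low genes in WT replicate 2, where 3 reads are worth 35.06 normalized counts.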

Other observations

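The tests near the insertions and of root tissue were planned before the data were examined, and that of shared reads was chosen after. Beyond the named lists, genes with the term response to karrikin (29 of 67, against 10.7 by chance, adjusted p = 4e-06), response to chitin (21 of 55, against 8.78) and oligopeptide transport (17 of 40, against 6.38) were among those higher by at least 1 in T12. In T34 lipid transport had 23 of 57 against 9.99 and innate immune response 34 of 89 against 15.6. Genes of response to cold were lower by at least 1 in T34 for 23 of 120 against 11.2 (adjusted p = 0.0396).

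Segments of the parent accession linked to the gip1 and gip2 insertions could add calls near them. Within 3 Mb of either gene, 756 of 1884 tested genes were called in T12 (40.1%) and 40.2% elsewhere, an odds ratio of 1.0 (95% interval 0.91 to 1.1, Fisher's exact test, two-sided p = 0.98). In T34 the odds ratio was 0.95 (0.86 to 1.04). These values argue against linked segments as a source of many extra calls. With 40.2% of genes called elsewhere, they cannot show whether single genes were called for this reason. Among the largest rises and falls under the rule, PEN1, FKF1, THI2.1 and AT4G13575 lie within 3 Mb of either gene. WT is a Ws x Col-0 cross, and accession differences elsewhere in the genome were not tested. Lower root hair genes, looked for as a sign of less root tissue, were not seen, with a median log2 fold change of 0.18 in T34. The root endodermis and uptake list had a median of -0.72 (5 of 10 genes fell, 2 rose) and the root meristem list -0.22, so the root lists disagree and a smaller share of root tissue stays open.

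Reads of genes high in the mutants were more frequent in WT replicate 2 than its depth gives. For 86 nuclear genes with at least 64-fold lower values in WT replicate 3 than in the mutants, chosen without use of WT replicates 1 and 2, WT replicate 2 had 864 reads and WT replicate 1 had 3464. Relative to their size factors this ratio was 4.75 (bootstrap 95% interval over genes 3.79 to 6.47), against 0.99 for the other nuclear genes. A candidate explanation is that a small number of reads from the mutant libraries were counted in WT libraries, where 864 reads equal 0.735% of the mean T12 count of these genes. A real difference between the WT samples stays open. If reads were shared, fold changes of the most induced genes are understated.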
